A study of Mus musculus with 31 samples.

How the data were processed

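Bulk messenger RNA was measured in 31 libraries of mouse tumours. The labels name RNA isolation with RNeasy columns from cell pellets or flash-frozen tissue, and strand-specific poly(A) libraries. Per the labels, the authors trimmed reads with Trimmomatic 0.32.48, aligned them to the mouse genome (mm10, GRCm38) with STAR 2.3.0 and counted reads per gene with featureCounts 1.4.4. The deposited values are raw counts of reads per gene, as whole numbers, not normalised. The annotation release, the strand setting of the counting and any filter before counting are not stated in the labels. The deposited table held 39017 genes, of which 8371 had 0 counts in every library, and no column of it was left unused. Gene symbols, identifiers and coordinates come from a mouse annotation of GRCm38, which held 37607 of the identifiers.

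The libraries fall into 8 groups, from 2 tumour models and 4 treatment arms, with 4 libraries in each group except 4T1 phenformin, which has 3, numbered 1, 2 and 4. Groups were taken from the library titles. The strain and cell line tags of the libraries name the other model than the titles do, so each group is called by its title throughout. The titles number the replicates within each group, but the labels do not state which replicates are separate animals, so every p-value measures the spread between these libraries. Total counts ran from 12160110 in MT control replicate 4 to 19849915 in 4T1 phenformin replicate 2.

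Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and quasi-likelihood F-tests were run in 1 fit for each model and 1 joint fit of all 8 groups for differences between models. This left 17445 genes for the 4T1 model, 17857 for the MT model and 18956 for the joint fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The interaction is the log2 fold change of the combination over phenformin minus that of poly I:C over control. CPM, the counts of a gene relative to library size on the usual scale of the edgeR cpm function, use TMM-scaled library sizes for named genes and are given as mean ± SD. Marker levels of single libraries (Sox10, Krt5, Acta1, Igkc, H2-Ea-ps) use the library totals, as do the figures.

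Before the data were examined, 33 gene lists were fixed, covering interferon and inflammatory signalling, antigen presentation, neutrophils and other leukocytes, other cell types of a tumour piece, metabolism, stress responses and the cell cycle. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists of a comparison. Camera asks whether the genes of a list rank higher or lower than the other genes. It was repeated with a correlation estimated from the data, and fry tested whether the genes of a list move one way. No camera call in any comparison held with the estimated correlation. Within each list, genes were also adjusted over the list alone.

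The genes named were also chosen by a rule fixed before the data were examined. It takes the 5 largest increases and the 5 largest decreases among called genes with an average log2 CPM of at least 1, an informative symbol and no overlap between the libraries of both groups. It adds up to 3 members with the smallest p of each list that camera called. It does the same, called or not, for the lists of interferon-stimulated genes, NF-kB targets, neutrophil markers, neutrophil effector genes and the integrated stress response. These parts of the rule were applied to the comparisons within a model, but not to the combination against phenformin. For differences between models it takes the 5 genes with the smallest p. Sox10, Krt5, Acta1, Igkc, H2-Ea-ps, Trp53, Cdkn2a, S100a8, Camp, Prtn3, Ltf, Elane and Cebpe were chosen after their values were seen.

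Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, at least 1 CPM in 4 libraries, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were limma voom with library quality weights, the log2 ratio of Krt5 to Sox10 as a covariate for the MT libraries, and fits without MT libraries with Sox10 above 10 CPM, without 4T1 libraries with Acta1 above 10 CPM, or without 4T1 libraries with Igkc above 100 CPM. The edgeR settings were tested on simulated data with 100 changed genes at each of 2 fold sizes, at the library totals of these libraries. All genes of a fit were given its 1 common dispersion. The changed genes were drawn only from genes with a mean above 1 CPM, and no differences in tissue content between libraries were simulated. Real genes vary in dispersion, so the shares recovered hold only for such genes at that common value. The uneven spread of Sox10-high and Krt5-high cells as the cause of the granule gene rise was weighed by 3 rules in turn, all after the gene values were seen. The first asked for at least 1 in 3 of these genes called with the covariate, and left that cause open in both arms. The next asked for a median 2 median SE above 0, counted against the cause in both arms, and was dropped, since the median mixes members that turned sign with members that shrank. The last, reported here, is fry on the list with the covariate, at a p adjusted over both arms, with its threshold set before it was run. It called the list higher in both arms. It is taken as deciding nothing, since it followed other rules and some members turned sign with the covariate. Regroupings of a comparison with 0 called genes were first counted as fitting chance, and are now taken as deciding nothing. The permutation test of Sox10 was also first counted as fitting a treatment effect, and is now taken as deciding nothing, since the split prompted it. Figures were drawn with matplotlib 3.10.9.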

Results

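Tumour RNA was profiled in 2 mouse breast tumour models, titled 4T1 and MT, each grown in syngeneic mice that received vehicle, phenformin, poly I:C or both agents. Phenformin is a biguanide that inhibits complex I of the mitochondrial respiratory chain, and poly I:C is a synthetic double-stranded RNA that activates Toll-like receptor 3. Each group held 4 libraries, except 4T1 phenformin with 3. Total counts per library ranged from 12160110 to 19849915. The titles and the strain and cell line tags name opposite models. H2-Ea-ps, which mice of some MHC haplotypes do not transcribe, measured 214 to 970 CPM in the 15 libraries titled 4T1 and 5.24 to 53 CPM in the 16 libraries titled MT. Groups below follow the titles.

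**Figure D1:**
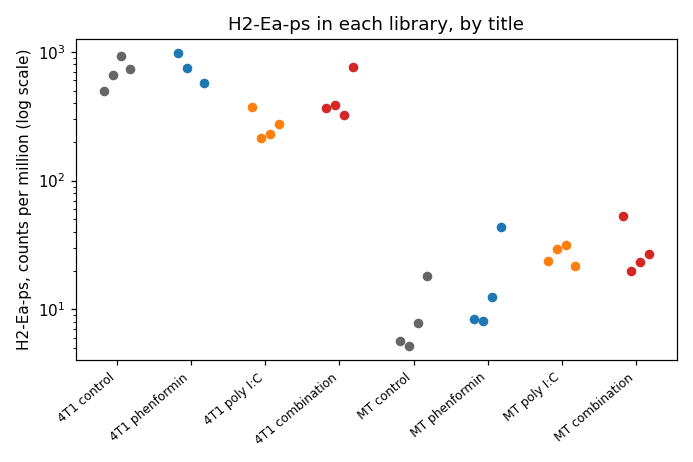
H2-Ea-ps in CPM of library totals on a logarithmic axis, one point per library, by the model that the title names. Libraries titled 4T1 lie between 214 and 970 CPM and libraries titled MT between 5.24 and 53 CPM.

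**Figure D2:**
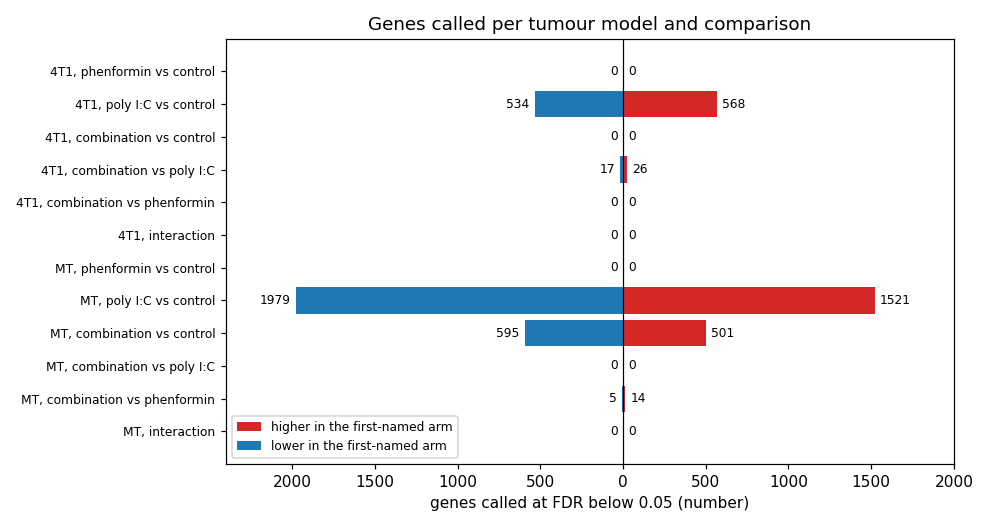
Number of genes called higher (bars above 0) and lower (bars below 0) by edgeR at an adjusted p under 0.05 in each comparison. The largest treatment count is 3500 genes for poly I:C against control in MT tumours, and phenformin against control gives 0 genes in both models.

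The first question in the 4T1 model was what poly I:C alone did to the tumours (n = 4 against n = 4). Inflammatory genes rose, and genes of macrophages and of MHC class II fell. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, GRCm38 chromosome 11, 78920787 to 78960254), rose from 21.4 ± 9.09 to 175 ± 104 CPM, a log2 fold change of 3.03 ± 0.58 (SE, adjusted p = 0.012). Ptgs2, which makes prostaglandins (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), rose from 60.7 ± 17.9 to 254 ± 122 CPM (2.06 ± 0.38, adjusted p = 0.0112). The cytokine gene Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) rose from 1.23 ± 0.457 to 7.63 ± 4.47 CPM (2.63 ± 0.51, adjusted p = 0.0128). Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), fell from 2014 ± 357 to 771 ± 208 CPM (-1.38 ± 0.22, adjusted p = 0.00694).

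By list, 9 of 30 NF-kB targets and inflammatory cytokines rose in the 4T1 tumours given poly I:C, and 14 rose when adjusted over the list alone. Neutrophil markers rose for 6 of 25 genes (17 adjusted over the list alone), among them the neutrophil collagenase Mmp8 (2.68 ± 0.54, adjusted p = 0.0143), the decoy receptor Il1r2 (1.57 ± 0.37) and Acod1, which makes itaconate (2.28 ± 0.61). Mmp8 missed the threshold without 4T1 control replicate 3 (adjusted p = 0.0509), and the Il1r2 and Acod1 calls were lost in 5 and 7 of the 8 fits with 1 library left out. Interferon-stimulated genes rose for 4 of 32 genes (15 adjusted over the list alone), with Rsad2 at 1.60 ± 0.43 and Herc6 at 0.58 ± 0.15. Both calls were lost in 7 of those 8 fits. Camera ranked these lists above other genes (adjusted p = 2.45e-06, 8.4e-06 and 4.64e-07), but gave an adjusted p = 0.686 with an estimated correlation for each. Neutrophil effector and oxidative burst genes went both ways, with Nos2 higher and Cybb, a subunit of the NADPH oxidase, lower (-0.67 ± 0.16, adjusted p = 0.0273). In that list 16 of 18 genes did not pass (adjusted over the list alone, 1 rose and 4 fell). Granule genes of immature neutrophils gave 1 lower gene of 8, over all genes and adjusted over the list alone.

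Macrophage markers fell for 6 of 18 genes in the same comparison (11 adjusted over the list alone). Apoe, which carries lipids, fell by 1.27 ± 0.19 on the log2 scale (adjusted p = 0.00538), and the complement genes C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) and C1qb changed by -1.12 ± 0.17 and -1.21 ± 0.21. Of the MHC class II genes 7 of 11 fell, over all genes and adjusted over the list alone, including H2-Ab1 (-1.44 ± 0.26) and H2-Aa (-1.36 ± 0.26). Fibroblast and matrix genes rose for 14 of 22 genes (19 adjusted over the list alone), such as Tagln, a smooth muscle and myofibroblast protein, at 1.46 ± 0.24 and the collagen genes Col5a1 and Col5a2 at 1.19 ± 0.22 and 1.25 ± 0.24. Glycolysis genes rose for 9 of 21 (14 adjusted over the list alone; Pgam1 0.63 ± 0.12). In the hypoxia-responsive list 9 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), with Egln1, an oxygen sensor, at 0.58 ± 0.10 and Plod2 at 0.94 ± 0.19. Camera called all 5 of these lists (adjusted p from 5.09e-12 for fibroblast genes to 1.05e-06 for glycolysis), with an adjusted p = 0.522 with an estimated correlation for each.

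Smaller shifts followed in other lists of the poly I:C comparison in 4T1 tumours. Cholesterol synthesis genes rose for 4 of 22 (5 adjusted over the list alone; Sc5d 0.49 ± 0.10) and G2 and M phase genes for 2 of 22 (5 adjusted over the list alone). Camera called both higher, with an adjusted p = 0.686 with an estimated correlation. Camera also called dendritic cell markers lower (1 of 13 fell, Itgax; adjusted p = 0.686 with an estimated correlation), adipocyte markers lower (1 of 13, Pnpla2; adjusted p = 0.713 with an estimated correlation). It called complex I subunits lower (1 of 36, Ndufb11, and 0 adjusted over the list alone; adjusted p = 0.697 with an estimated correlation) and S phase genes higher (0 of 22; adjusted p = 0.713 with an estimated correlation). The complex I call was lost without control replicate 4 (adjusted p = 0.129) or poly I:C replicate 4 (adjusted p = 0.0966), and the dendritic cell call without the latter (adjusted p = 0.136). The S phase and adipocyte calls were lost in 3 and 4 of the 8 fits with 1 library left out. Of the p53 target and apoptosis genes 2 of 20 rose (4 adjusted over the list alone) and of the oxidative stress genes 1 of 20, without a camera call. The integrated stress response list split, with 2 genes higher, 2 lower and 21 of 25 not passing (adjusted over the list alone, 4 higher and 6 lower). Among the largest decreases were C6, a terminal complement component (-3.11 ± 0.50, 24.4 ± 8.88 to 2.85 ± 1.65 CPM), Mgl2, a macrophage lectin (-3.02 ± 0.51) and Fetub (-3.02 ± 0.44). Slc6a2 fell by 3.46 ± 0.72 and Mcpt2 by 3.43 ± 0.91 on the log2 scale, and Meg3 (2.40 ± 0.61) and Slc9b2 (2.39 ± 0.57) were among the largest increases.

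**Figure D3:**
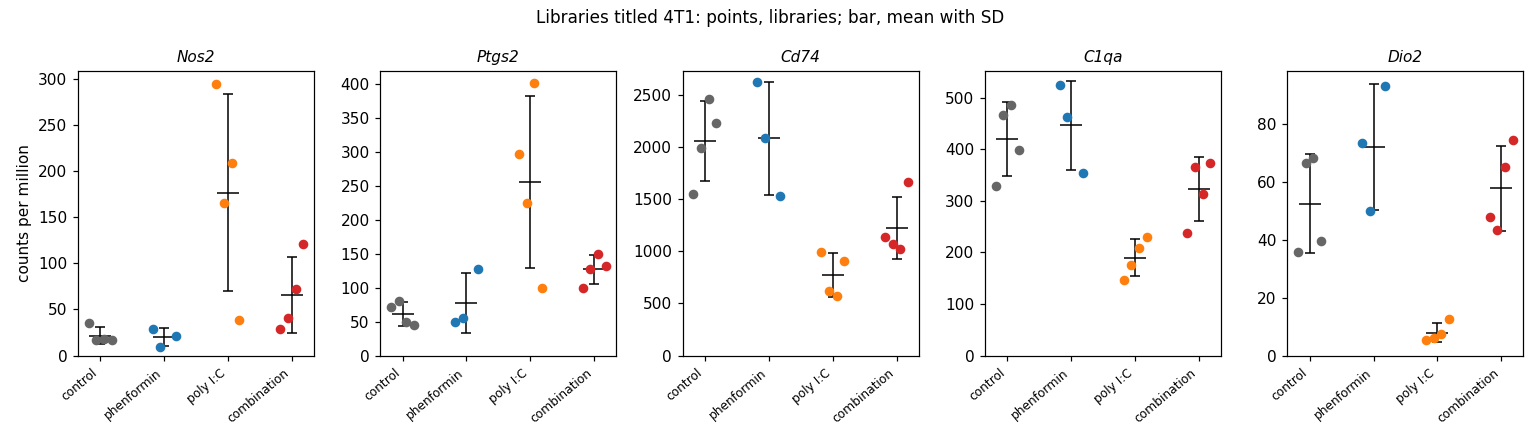
CPM of library totals for Nos2, Ptgs2, Cd74, C1qa and Dio2 in each 4T1 library by arm, with the mean and SD of each arm. The means of Nos2 and Ptgs2 are highest and those of Cd74, C1qa and Dio2 lowest in the poly I:C arm, with Dio2 at 5.24 CPM in the lowest library.

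In total edgeR called 1102 of 17445 genes for poly I:C in the 4T1 model, 568 higher and 534 lower. DESeq2 called 1959 and voom 2863. Skeletal muscle markers were high in some libraries of the treated arms: Acta1, muscle actin, was at most 0.758 CPM in the 4 controls, and reached 18.5 and 33.0 CPM in poly I:C replicates 3 and 2. It was 98.8 and 227 CPM in combination replicates 4 and 1, but 5.16 and 2.72 CPM in combination replicates 2 and 3. In poly I:C replicates 1 and 4 it was 3.73 and 1.46 CPM. Of the muscle markers 1 of 15 rose with poly I:C (4 adjusted over the list alone), Myh4, at 9.95 ± 2.78 (adjusted p = 0.0478). Myh4 was 0.0263 ± 0.0304 CPM in controls and 33.7 ± 43.5 CPM with poly I:C, so this fold rests on almost no counts in controls. For the list camera gave an adjusted p = 0.00168 that became an adjusted p = 0.699 with an estimated correlation. Igkc, an antibody light chain, was 671 CPM in poly I:C replicate 1 and 110 CPM in control replicate 4. The call count fell to 0 without the 5 libraries with Acta1 above 10 CPM and to 259 without the 3 with Igkc above 100 CPM. It was 455, 320 and 447 without control replicates 2, 3 and 4, 289 without poly I:C replicate 2 and 1986 without poly I:C replicate 4. It was 401 when only these groups were fitted, and 23 of the 45 named calls held whichever library was left out.

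What phenformin did in 4T1 tumours also given poly I:C was asked by the combination against poly I:C (n = 4 each). Whether it changed the response to poly I:C itself is asked by the interaction, given below. Dio2, the enzyme that activates thyroid hormone (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438), was higher with the combination, at 58.6 ± 14.1 against 7.9 ± 3.49 CPM (2.89 ± 0.33, adjusted p = 0.00525), and stood at 51.5 ± 16.6 CPM in controls. The imprinted RNA gene H19 rose by 2.12 ± 0.40 (adjusted p = 0.0463), Galnt15 by 2.11 ± 0.34, Thsd4 by 1.61 ± 0.30 and Kitl, the ligand of the Kit receptor, by 1.46 ± 0.27. Among lower genes were the metalloprotease gene Adam12 (-1.50 ± 0.22, 33.3 ± 3.13 against 93.9 ± 24.9 CPM), Prokr2 (-1.66 ± 0.29), Col5a3 (-1.53 ± 0.29), Tfpi2 (-1.44 ± 0.24) and Bcat1 (-1.35 ± 0.23). In the NF-kB list 0 of 30 genes passed over all genes. Adjusted over the list alone, 17 fell and 1 rose (Il6 -2.39 ± 0.50, adjusted p = 0.0514 over all genes). Fibroblast and matrix genes gave 19 lower and 1 higher of 22 adjusted over the list alone, cholesterol synthesis genes 10 lower of 22 (1 over all genes, Cyp51, -0.71 ± 0.13) and macrophage markers 6 higher of 18. Camera called these 4 lists, each with an adjusted p = 0.821 with an estimated correlation.

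Neutrophil markers were called lower by camera in that comparison (13 of 25 adjusted over the list alone, 0 over all genes), and so were interferon-stimulated genes (0 of 32), a call lost without poly I:C replicate 3 (adjusted p = 0.0518) or combination replicate 2 (adjusted p = 0.319). MHC class I genes were called higher (3 of 19 adjusted over the list alone; B2m 0.35 ± 0.09), and MHC class II genes too (5 of 11 adjusted over the list alone), although their mean of -0.12 lies below 0 and their median of 0.58 above it. That median was 0.29 without combination replicate 4 (adjusted p = 0.12), and the call was also lost without poly I:C replicate 3 (adjusted p = 0.0699). Muscle markers (0 of 15) and complex I subunits (0 of 36) were also called higher. The complex I call was lost without poly I:C replicate 4 (adjusted p = 0.218) or combination replicate 4 (adjusted p = 0.204). All of these calls had an adjusted p = 0.884 with an estimated correlation. The count was small: edgeR called 43 genes (26 higher, 17 lower; 3413 at an unadjusted p under 0.05), against 960 by DESeq2 and 1577 by voom. The count was 1412 without poly I:C replicate 4, 2, 1 and 16 without poly I:C replicates 1, 2 and 3, and 4, 1, 1 and 1 without combination replicates 1, 2, 3 and 4. Only the Dio2 call held each time, and it ended without the libraries with Acta1 above 10 CPM (log2 fold change 2.60, adjusted p = 0.603), which left 0 genes, as did a fit of only these groups.

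Against control, the 4T1 combination tumours (n = 4 each) gave 0 of 17445 genes in edgeR, with 2072 at an unadjusted p under 0.05; DESeq2 called 391 and voom 226. Adjusted over the list alone, dendritic cell markers were lower for 7 of 13 genes (Cd209a -5.03 ± 1.19, 0.0464 ± 0.0612 against 1.68 ± 1.03 CPM) and MHC class II genes for 4 of 11 (Cd74 -0.70 ± 0.22). Hypoxia-responsive genes were higher for 12 of 20 (Kdm3a 0.60 ± 0.11), glycolysis genes for 10 of 21 (Pkm 0.32 ± 0.09), muscle markers for 15 of 15 and oxidative stress genes for 2 of 20 (Gclm, which makes glutathione, 0.46 ± 0.08). Over all genes none of these passed. Camera called the lists, with an adjusted p = 0.308 with an estimated correlation for dendritic cell and oxidative stress genes and adjusted p = 0.503 with an estimated correlation for MHC class II. It gave adjusted p = 0.482 with an estimated correlation for hypoxia, adjusted p = 0.361 with an estimated correlation for glycolysis and adjusted p = 0.453 with an estimated correlation for muscle. It also called interferon-stimulated, MHC class I and G2 and M phase genes higher and macrophage, B cell, adipocyte and cholesterol synthesis genes lower. This was without a gene passing in any of them and with an adjusted p = 0.949 with an estimated correlation for each. Without the libraries with Acta1 above 10 CPM the interferon-stimulated and MHC class I calls were lost and both tests turned direction. The adipocyte call was lost without combination replicate 1 (adjusted p = 0.0665), and the oxidative stress call without control replicate 1 or 2 (adjusted p = 0.0528 and 0.0574). Of the 13 list calls 6 held whichever library was left out. The gene count was 1 without control replicate 4 and 32 when only these groups were fitted.

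Phenformin alone in 4T1 tumours (n = 3 against n = 4) also gave 0 genes in edgeR, with 1753 at an unadjusted p under 0.05, 175 by DESeq2 and 0 by voom. Adjusted over the list alone, fibroblast and matrix genes were lower for 11 of 22 (Fbln1 -1.28 ± 0.29) and hypoxia-responsive genes higher for 1 of 20 (Ddit4). Camera called both lists and also endothelial, adipocyte and epithelial markers (lower; 0 of 16, 0 of 13 and 0 of 20 passing) and T cell, checkpoint, muscle and complex I genes (higher; 0 of 19, 0 of 12, 0 of 15 and 0 of 36). Each of these 9 calls had an adjusted p = 0.983 with an estimated correlation. T cell and epithelial calls were lost without phenformin replicate 2 (adjusted p = 0.773 for each), whose Igkc was 610 CPM. The checkpoint call was lost without that library (adjusted p = 0.111) or phenformin replicate 1 (adjusted p = 0.189), and the epithelial call also without control replicate 4 (adjusted p = 0.119). The muscle and hypoxia calls were lost without phenformin replicate 4 (adjusted p = 0.436 and 0.337), whose Acta1 was 40.1 CPM. The combination against phenformin gave 0 genes (2174 at an unadjusted p under 0.05; DESeq2 179, voom 0). Adjusted over the list alone, 15 of 22 fibroblast genes were higher (adjusted p = 0.535 with an estimated correlation) and 11 of 13 dendritic cell markers lower (adjusted p = 0.456 with an estimated correlation). Camera also called T cell (0 of 19) and B and plasma cell markers (0 of 14) lower, each with an adjusted p = 0.738 with an estimated correlation. Both calls were lost without phenformin replicate 2 (adjusted p = 0.0541 and 0.153). The interaction gave 0 genes (1628 at an unadjusted p under 0.05; DESeq2 36, voom 2) and 19 without poly I:C replicate 4. Its camera calls included NF-kB targets and cholesterol synthesis genes, lower than the sum of both single effects, and macrophage markers, higher. These had 0 genes passing, and an adjusted p = 0.846 with an estimated correlation for each. In simulated libraries the 4T1 comparisons recovered 47% to 65% of 2-fold and 99% to 100% of 4-fold changes, and the interaction 21% and 97%.

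Libraries of the MT model differed within groups. Sox10, a neural crest transcription factor (ENSMUSG00000033006, chromosome 15, 79154908 to 79165240), measured 168, 211 and 171 CPM in control replicates 1, 2 and 3, 188 and 185 CPM in phenformin replicates 1 and 2, and 34.4 CPM in phenformin replicate 3. It was 1.32 CPM in control replicate 4, 2.82 CPM in phenformin replicate 4 and between 0.699 and 3.19 CPM in all poly I:C and combination libraries. Krt5, a basal keratin (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898), ran the other way, at 20.7 to 29.0 CPM in control replicates 1 to 3 and 2223 CPM in control replicate 4, and 344 to 2535 CPM in poly I:C and combination libraries. Every MT comparison of a poly I:C arm with control or phenformin therefore also compares libraries of unlike Sox10 and Krt5 level. Krt5 was also 1653 and 1120 CPM in phenformin replicates 3 and 4. Phenformin against control, and the interaction, are therefore uneven in these genes too. Keratinocyte and skin genes made up 0.00666% to 0.00836% of counts in control replicates 1 to 3 and 0.0351% in control replicate 4. Their share was 0.0274% to 0.0437% in poly I:C and 0.00833% to 0.0524% in combination libraries. Whether Krt5 came from tumour or skin cells was not tested.

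**Figure D4:**
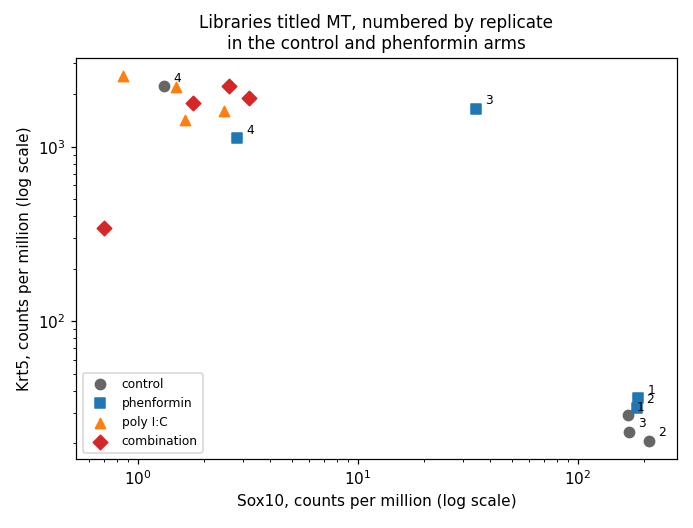
Sox10 against Krt5 in each MT library, in CPM of library totals on logarithmic axes, with arms by colour and replicate numbers for control and phenformin. Control replicates 1 to 3 and phenformin replicates 1 and 2 are high in Sox10, at 168 to 211 CPM, and all 8 poly I:C and combination libraries lie at or below 3.19 CPM.

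For poly I:C alone in the MT model (n = 4 against n = 4), myeloid genes rose. Ngp, a granule protein of immature neutrophils (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), rose from 0.793 ± 0.384 to 42 ± 15.7 CPM (5.74 ± 0.89, adjusted p = 0.00197), and myeloperoxidase, Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), from 0.387 ± 0.283 to 9.02 ± 4.15 CPM (4.57 ± 0.76). Csf1r, the macrophage growth factor receptor (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), rose from 57 ± 6.58 to 197 ± 40.9 CPM (1.79 ± 0.21, adjusted p = 0.000898). The chemokine gene Cxcl9 rose from 770 ± 243 to 2708 ± 240 CPM (1.81 ± 0.42), a call that ended with the log2 ratio of Krt5 to Sox10 as a covariate (1.14, adjusted p = 0.186). Subunits of complex I fell, such as Ndufa2 (ENSMUSG00000014294, chromosome 18, 36742332 to 36744557), from 89.2 ± 14 to 45.6 ± 7.34 CPM (-0.97 ± 0.14, adjusted p = 0.00163).

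Neutrophil markers rose for 20 of 26 genes and fell for 2 in these MT tumours (21 and 3 adjusted over the list alone). Granule genes of immature stages rose for 8 of 11 and fell for 1 (9 and 1 adjusted over the list alone). Adding the log2 ratio of Krt5 to Sox10 as a covariate left 3 of these 11 called. Prtn3, the lower gene, then turned from -2.52 to 1.15 and Camp from -1.99 to 2.498. Effector genes rose for 10 of 18 (13 adjusted over the list alone; Cybb 1.60 ± 0.24, Fasl 1.97 ± 0.38). Ctsg, a granule protease, rose by 5.16 ± 1.09 and Mmp8 by 3.39 ± 0.54. With that covariate the Fasl (1.29, adjusted p = 0.0645) and Ctsg (3.50, adjusted p = 0.119) calls ended, while Cybb and Mmp8 kept theirs. Stfa2 (5.42 ± 0.70) and BC100530 (4.82 ± 0.82) are near-identical copies of 1 gene family, so reads may be shared between them. Macrophage markers rose for 15 of 17 (16 adjusted over the list alone), inflammatory monocyte markers for 8 of 11 (9 adjusted over the list alone; Ccr2 1.64 ± 0.29). Double-stranded RNA and Toll-like receptor genes rose for 7 of 23, over all genes and adjusted over the list alone (Tlr4 1.62 ± 0.16, Tlr7 2.14 ± 0.36, Tlr8 2.56 ± 0.46). Complex I subunits fell for 25 of 36 (29 adjusted over the list alone). Camera called these 7 lists, with adjusted p from 1.85e-12 for complex I to 0.000423 for the receptor list, and gave each an adjusted p = 0.158 with an estimated correlation.

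Lymphoid and antigen presentation lists followed in MT tumours given poly I:C. Checkpoint genes rose for 8 of 12 (11 adjusted over the list alone; Pdcd1lg2 2.55 ± 0.36, Cd274 1.49 ± 0.24, Havcr2 1.94 ± 0.24; adjusted p = 0.164 with an estimated correlation). NK and cytotoxic lymphocyte genes rose for 6 of 16 (11 adjusted over the list alone; Prf1, perforin, 2.13 ± 0.38, Ifng 1.67 ± 0.39; adjusted p = 0.283 with an estimated correlation). MHC class II genes rose for 6 of 11 (7 adjusted over the list alone; Ciita 1.06 ± 0.22; adjusted p = 0.332 with an estimated correlation). NF-kB targets rose for 10 of 29 (14 higher and 1 lower adjusted over the list alone; Vcam1 2.16 ± 0.38; adjusted p = 0.279 with an estimated correlation) and interferon-gamma-inducible genes did for 7 of 24, over all genes and adjusted over the list alone (Serpina3g 1.71 ± 0.19; adjusted p = 0.522 with an estimated correlation). Dendritic cell markers rose for 2 of 13 (4 adjusted over the list alone; Itgax 1.79 ± 0.28; adjusted p = 0.522 with an estimated correlation), and T cell markers gave 0 of 19 though camera called them (adjusted p = 0.619 with an estimated correlation). The T cell median turned to -0.44 with the Krt5 to Sox10 covariate and to -0.34 without the libraries with Sox10 above 10 CPM. Igkc was 2805 CPM in poly I:C replicate 3, 9108 and 2209 CPM in combination replicates 1 and 4, 3329 CPM in phenformin replicate 4 and 2.95 to 311 CPM in controls. Interferon-stimulated genes rose for 2 of 32 (Trim30a 1.65 ± 0.43, Ifit2), 0 adjusted over the list alone, with no camera call. Both calls ended with that covariate, at 0.59 (adjusted p = 0.141) and 0.80 (adjusted p = 0.317). The Ifng (1.67, adjusted p = 0.0827) and Ciita (1.02, adjusted p = 0.0532) calls ended with it too, while Prf1 shrank to 1.30 and kept its call. MHC class I genes gave 1 higher and 1 lower of 19 (adjusted over the list alone, 2 and 3) and no call.

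Stromal and red cell lists rose too in the MT poly I:C comparison. Endothelial markers rose for 13 of 16 (15 adjusted over the list alone; Cdh5 1.47 ± 0.27; adjusted p = 0.279 with an estimated correlation) and fibroblast genes for 10 of 22, over all genes and adjusted over the list alone (Pdgfra 1.62 ± 0.30; adjusted p = 0.283 with an estimated correlation). Erythroid genes rose for 6 of 7 (7 adjusted over the list alone; Slc4a1 4.32 ± 0.88; adjusted p = 0.283 with an estimated correlation) and adipocyte markers for 1 of 15 (12 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation). Poly I:C replicate 2 stood apart, with adipocyte genes at 0.213% of counts (others 0.0401% to 0.0645%) and erythroid genes at 0.165% (others 0.047% to 0.0855%), and both calls held without it. G2 and M phase genes fell for 6 of 22 (7 adjusted over the list alone; Aurka -1.83 ± 0.36, Ube2c -1.63 ± 0.26; adjusted p = 0.373 with an estimated correlation). Cholesterol synthesis genes fell for 6 of 21 (11 adjusted over the list alone; Fdps -1.30 ± 0.31; adjusted p = 0.522 with an estimated correlation). The integrated stress response list gave 4 lower and 1 higher of 24 genes (adjusted over the list alone, 5 and 2; Psat1 -0.74 ± 0.19, Atf4 -0.71 ± 0.19) without a call. The largest decreases were Fkbp6 (-8.35 ± 1.71), Il12a (-6.24 ± 1.38), Pipox (-5.99 ± 1.43), Nptx1 (-3.99 ± 1.07) and Trpm3 (-3.80 ± 0.89). With the Krt5 to Sox10 covariate these 5 calls ended, at -3.11, -1.92, -1.81, -0.31 and -0.77. The Aurka (-0.56), Fdps (-0.50), Psat1 (-0.23), Atf4 (-0.65) and Pdgfra (1.27, adjusted p = 0.0573) calls ended too, while Ube2c shrank to -0.82 and kept its call.

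**Figure D5:**
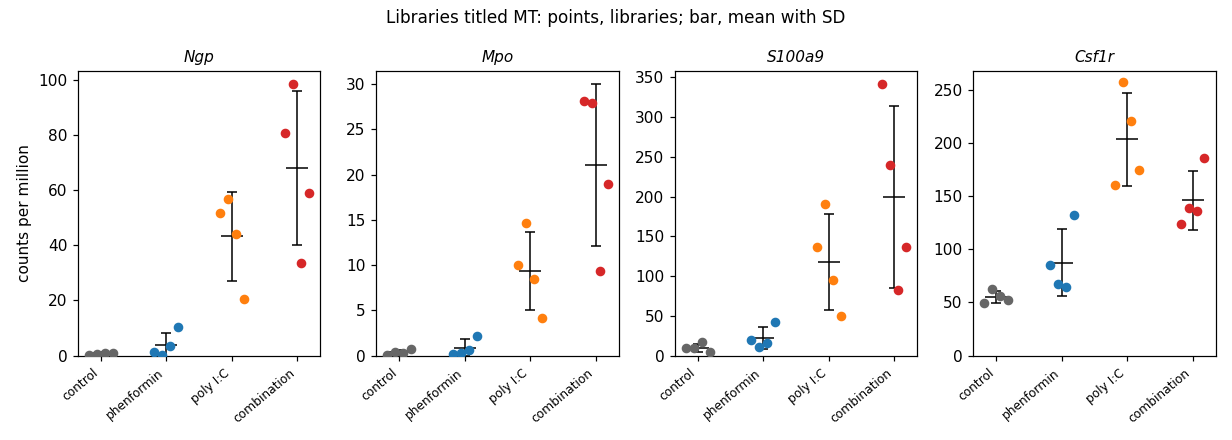
CPM of library totals for Ngp, Mpo, S100a9 and Csf1r in each MT library by arm, with the mean and SD of each arm. All poly I:C and combination libraries lie above all controls for each gene, with Ngp between 20.5 and 98.4 CPM in them.

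EdgeR called 3500 of 17857 genes for poly I:C in the MT model, 1521 higher and 1979 lower; voom called 10642. The count was 2042, 1512, 2139 and 6256 without control replicates 1, 2, 3 and 4, and 1664, 1970 and 2154 without poly I:C replicates 2, 3 and 4. All 20 list calls and 53 of the 66 named genes held each time. With the log2 ratio of Krt5 to Sox10 as a covariate 1569 genes were called, 811 of them among the 3500, and without the 6 libraries with Sox10 above 10 CPM, which leaves 1 control, 0 genes.

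The combination against control in the MT model (n = 4 each) asked what both agents did together. Neutrophil genes rose again. Ngp reached 66.2 ± 27.2 CPM (6.40 ± 0.92, adjusted p = 0.00638), Mpo 20.5 ± 8.72 CPM (5.76 ± 0.79), and S100a9, a subunit of calprotectin (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), rose from 10.5 ± 5.37 to 195 ± 113 CPM (4.21 ± 0.59, adjusted p = 0.00607). S100a8, the other subunit, had the lower mean, at 172.5 ± 117 against 1092 ± 1030 CPM, and did not pass (-2.66 ± 1.25, adjusted p = 0.169). Neutrophil markers rose for 18 of 26 and fell for 1 (19 and 2 adjusted over the list alone), and granule genes rose for 7 of 11 (9 adjusted over the list alone), each with an adjusted p = 0.121 with an estimated correlation. Macrophage markers rose for 9 of 17 (15 adjusted over the list alone), and effector genes for 8 of 18 (10 adjusted over the list alone). Monocyte markers rose for 5 of 11 (8 adjusted over the list alone), checkpoint genes for 4 of 12 (12 adjusted over the list alone) and receptor genes for 4 of 23, over all genes and adjusted over the list alone (Tlr4 0.95 ± 0.16). Each of these 5 lists had an adjusted p = 0.216 with an estimated correlation. MHC class II genes rose for 6 of 11 (9 adjusted over the list alone; Ctss 1.32 ± 0.23) and NK genes for 3 of 16 (9 adjusted over the list alone; Klrk1 1.19 ± 0.24). NF-kB targets rose for 5 and fell for 1 of 29 (16 and 1 adjusted over the list alone), and these 3 lists each had an adjusted p = 0.26 with an estimated correlation. Complex I subunits fell for 3 of 36 (8 adjusted over the list alone; Ndufb3 -0.48 ± 0.10; adjusted p = 0.46 with an estimated correlation). Cyp24a1 stood at 6.43 ± 5.17 CPM in controls and was listed at 0 in all 4 combination libraries.

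Of 17857 genes, edgeR called 1096 for the MT combination against control, 501 higher and 595 lower, DESeq2 2901 and voom 9378. The count was 19, 24, 208 and 5375 without control replicates 1, 2, 3 and 4, and 673, 110, 103 and 62 without combination replicates 1, 2, 3 and 4, and 51 when only these groups were fitted. Of the 52 named calls 6, Ngp, Mpo, S100a9, Mmp8, Ms4a3 and Stfa2, held each time. It was 0 without the libraries with Sox10 above 10 CPM and 0 with the Krt5 to Sox10 covariate. With the covariate S100a9 stood at 4.31 ± 0.86 (adjusted p = 0.125), where its SE grew, and Ngp at 4.92 ± 1.03 (adjusted p = 0.142), where its fold also shrank. The median of the granule genes was 3.12 with it and 2.89 without, but Camp (-1.14 to 3.12) and Prtn3 (-1.30 to 2.11) turned sign. Mpo (5.76 to 4.61 ± 0.84), Ctsg (6.24 to 4.82), Ms4a3 (7.32 to 6.03 ± 1.23) and Ltf (2.10 to 0.60) shrank, and Elane (4.32 to 4.47) and Cebpe (2.89 to 2.93) hardly moved.

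Whether phenformin added to poly I:C in the MT model was asked by the combination against poly I:C (n = 4 each). No gene passed in edgeR (0 of 17857, with 1076 at an unadjusted p under 0.05); DESeq2 called 3 and voom 973. Complex I subunits were higher for 14 of 36 genes adjusted over the list alone, with a median of 0.28 (Ndufs7 0.52 ± 0.13, adjusted p = 0.817 over all genes), and camera called the list (adjusted p = 3.53e-16), with an adjusted p = 0.58 with an estimated correlation. Erythroid genes were lower for 2 of 7 and Toll-like receptor genes for 2 of 23 adjusted over the list alone (Tlr8 -1.57 ± 0.44). Camera called macrophage (0 of 17) and fibroblast genes (0 of 22) lower and granule genes (0 of 11) higher, all of them with an adjusted p = 0.58 with an estimated correlation. Of the 14 list calls of this comparison 4 held whichever library was left out. The interaction gave 0 genes (1769 at an unadjusted p under 0.05; DESeq2 33, voom 0), and it spans arms of unlike Sox10 and Krt5 level. Adjusted over the list alone, 23 of 36 complex I subunits were higher than the sum of both single effects (median 0.45), and 10 of 16 endothelial, 8 of 22 fibroblast and 4 of 17 macrophage genes lower, each with an adjusted p = 0.261 with an estimated correlation. Simulated changes were recovered for 5% to 10% of genes at 2-fold and 68% to 75% at 4-fold in the MT comparisons, and for 0% and 4% in the interaction. These shares hold at the common dispersion of 0.181. The 3500 genes called for poly I:C had a median size of 0.957 and a median SE of 0.236, so the shares do not describe such genes.

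Phenformin alone in the MT model (n = 4 each) gave 0 genes in edgeR, with 1084 at an unadjusted p under 0.05, 19 by DESeq2 and 0 by voom. Endothelial markers were higher for 10 of 16 genes adjusted over the list alone (Tie1 0.95 ± 0.26, adjusted p = 0.791 over all genes) and camera called the list (adjusted p = 4.36e-12), with an adjusted p = 0.343 with an estimated correlation. It also called complex I subunits lower (0 of 36, median -0.16; adjusted p = 0.343 with an estimated correlation), mitochondrially encoded genes higher (0 of 9, median 0.71, and -0.76 without the libraries with Sox10 above 10 CPM; adjusted p = 0.506 with an estimated correlation) and neutrophil markers higher (0 of 26; adjusted p = 0.343 with an estimated correlation). The neutrophil call was lost without control replicate 4 (adjusted p = 0.0613). Krt5 was high in phenformin replicates 3 and 4 (1653 and 1120 CPM) but among controls only in replicate 4. All of these calls therefore also compare libraries of unlike Krt5 level. The combination against phenformin gave 19 genes, 14 higher and 5 lower (2354 at an unadjusted p under 0.05; DESeq2 262, voom 5486). Neutrophil markers rose for 5 of 26 (17 higher and 2 lower adjusted over the list alone) and granule genes for 2 of 11 (7 adjusted over the list alone), both with an adjusted p = 0.0761 with an estimated correlation. Keratinocyte markers were called higher with 0 of 7 passing (adjusted p = 0.659 with an estimated correlation), but their median turned to -0.17 with the Krt5 to Sox10 covariate. The 19 became 3, 1, 4 and 86 without phenformin replicates 1, 2, 3 and 4, and 2, 1, 8 and 1 without combination replicates 1, 2, 3 and 4. They became 1 with the Krt5 to Sox10 covariate, and 0 when only these groups were fitted or without the libraries with Sox10 above 10 CPM.

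The response to poly I:C differed between the models, as tested by the difference of log2 fold changes, 4T1 minus MT. Macrophage markers fell for 6 of 18 genes in 4T1 and rose for 15 of 17 in MT tumours. Among the 5 genes with the smallest p the difference was -2.72 ± 0.30 for Csf1r (adjusted p = 1.54e-05), -2.56 ± 0.29 for C1qa, -2.54 ± 0.30 for Ctss, a lysosomal protease, -3.62 ± 0.41 for the serotonin receptor gene Htr7 and -1.76 ± 0.21 for Atp13a2. Macrophage markers differed in this direction for 15 of 18 genes (16 adjusted over the list alone; adjusted p = 0.0896 with an estimated correlation), and MHC class II genes for 8 of 11, over all genes and adjusted over the list alone. So did effector genes for 9 of 18 (12 adjusted over the list alone) and checkpoint genes for 6 of 12 (7 adjusted over the list alone), and these last 3 lists had an adjusted p = 0.107 with an estimated correlation. In the other direction, complex I subunits differed for 11 of 36 (12 adjusted over the list alone), cholesterol synthesis genes for 8 of 22 (13 adjusted over the list alone) and G2 and M phase genes for 6 of 22 (11 adjusted over the list alone), each with an adjusted p = 0.279 with an estimated correlation. Hypoxia-responsive genes differed for 4 of 20 (9 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation).

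In all, 2108 of 18956 genes differed in their response to poly I:C (1080 with a positive and 1028 with a negative difference), and voom called 8119. The count was 1308 without 4T1 control replicate 3, 1199 and 4438 without MT control replicates 2 and 4, and 1298 without MT poly I:C replicate 2. The named differences held each time. It was 1100 with the Krt5 to Sox10 covariate, 450 without MT libraries with Sox10 above 10 CPM, 927 without 4T1 libraries with Acta1 above 10 CPM and 1423 without those with Igkc above 100 CPM.

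The response to the combination differed between the models for 864 genes, 429 with a positive and 435 with a negative difference. Ngp differed by -6.35 ± 0.98 (adjusted p = 0.00226), with 6.1 ± 3.19 CPM in 4T1 and 66.2 ± 27.2 CPM in MT combination tumours against 5.86 ± 3.02 and 0.793 ± 0.384 CPM in the controls. The chemokine receptor gene Ccr2 (-2.87 ± 0.45), Nfam1 (-2.47 ± 0.36) and Htr7 (-2.88 ± 0.40) also differed, and so did the cell cycle inhibitor gene Cdkn1b (0.87 ± 0.12). Granule genes differed for 6 of 12 (9 adjusted over the list alone; adjusted p = 0.0941 with an estimated correlation) and neutrophil markers for 10 lower and 1 higher of 26 (14 and 1 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). DESeq2 called 2098 genes and voom 7366. The count was 325, 519 and 549 without 4T1 combination replicates 1, 2 and 3, 554, 392 and 262 without 4T1 control replicates 1, 2 and 3, and 351 without MT combination replicate 4. It was 230, 265, 449 and 4474 without MT control replicates 1, 2, 3 and 4, with the 5 named differences called each time. It was 465 without a low-count filter, 111 with the Krt5 to Sox10 covariate, 3 without MT libraries with Sox10 above 10 CPM, and 48 and 447 without 4T1 libraries with Acta1 above 10 or Igkc above 100 CPM.

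For phenformin the models differed for 0 genes in edgeR (1394 at an unadjusted p under 0.05; DESeq2 30, voom 0) and for 1 without 4T1 phenformin replicate 4 or without 4T1 libraries with Acta1 above 10 CPM. Per1, a clock gene, had the difference with the fifth smallest p, at 2.39 ± 0.54 (adjusted p = 0.322), with 91.9 ± 23.8 against 15 ± 1.57 CPM in 4T1 and 33.4 ± 16.7 against 28.3 ± 6.3 CPM in MT tumours. Adjusted over the list alone, 14 of 16 endothelial and 10 of 22 fibroblast genes had negative differences, each with an adjusted p = 0.158 with an estimated correlation. Simulated differences between models in the response to treatment were recovered for 1% to 3% of genes at 2-fold and 38% to 55% at 4-fold.

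Untreated tumours set the baseline for these differences (n = 4 each). Of 18956 genes, 9829 differed between the control groups, 5061 higher in 4T1 and 4768 lower. Ankrd1 was higher in 4T1 controls, at 142 ± 33.6 against 1.16 ± 0.301 CPM (7.02 ± 0.29), and so was Msln, mesothelin, by 10.79 ± 0.50. Rpl26 (-4.37 ± 0.18), Rpl21-ps8 (-9.28 ± 0.39) and Rplp0-ps1 (6.96 ± 0.32) belong to families of ribosomal genes and pseudogenes that share sequence, so their reads may be shared. Macrophage markers were higher in 4T1 for 14 of 18 genes (15 adjusted over the list alone), fibroblast genes for 19 of 22 and endothelial markers for 14 of 16, over all genes and adjusted over the list alone. Complex I subunits were lower for 30 of 36 and higher for 2, over all genes and adjusted over the list alone. Each of these calls had an adjusted p = 0.619 with an estimated correlation. Granule genes gave 3 higher and 3 lower of 12, over all genes and adjusted over the list alone, with a median of 1.32 and a mean of 0.21 but a camera test that pointed down. Epithelial markers gave 7 higher and 5 lower of 20, with a median of -0.49, a mean of -0.44 and a test that pointed up. Neither list was called. B and plasma cell markers were not called either here or for poly I:C in either model.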

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

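All tests named in this part for the Sox10 and Krt5 split, the label conflict and the muscle and lymphoid markers were chosen only after the values had been seen.

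Each sample group was searched for 1 library far from the others, in 112 groups of values, of which chance alone is taken to flag about 1 in 20, or 5.6. Adipocyte genes made up 0.213% of counts in MT poly I:C replicate 2 (others 0.0401% to 0.0645%), and mitochondrially encoded genes 4.08% there (others 1.41% to 1.58%). Erythroid genes made up 0.0235% in 4T1 control replicate 3 (others 0.014% to 0.015%) and 0.00301% in 4T1 combination replicate 4 (others 0.0181% to 0.0207%). Keratinocyte genes made up 0.0351% in MT control replicate 4 (others 0.00666% to 0.00836%), whose Krt5 was 2220 CPM (others 20.7 to 29). H2-Ea-ps was 767 CPM in 4T1 combination replicate 4 (others 324 to 383) and 43.4 CPM in MT phenformin replicate 4 (others 8.21 to 12.6). Sox10 was 2.27 CPM in 4T1 poly I:C replicate 3 (others 0.35 to 0.522).

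Mean log2 CPM of interferon-stimulated genes was 5.36 in 4T1 poly I:C replicate 4 (others 6.56 to 6.71) and 5.25 in 4T1 combination replicate 2 (others 6.2 to 6.24). That of the integrated stress response list was 4.46 in 4T1 poly I:C replicate 4 (others 4.67 to 4.71). NF-kB targets averaged 3.61 in MT control replicate 4 (others 2.91 to 3). Neutrophil markers averaged 2.86 in MT combination replicate 3 (others 3.72 to 3.88), and effector genes 5.82 in MT combination replicate 4 (others 5.37 to 5.42). B and plasma cell markers averaged 6.08 in 4T1 poly I:C replicate 1 (others -1.57 to -0.463) and 5.73 in MT control replicate 4 (others -1.03 to -0.00149).

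The effect of phenformin differed between the models for 15 gene lists, that of poly I:C for 24 and that of the combination for 23. Of these 6, 18 and 20 held whichever library was left out, and none held with an estimated correlation. The effect of poly I:C differed for 2108 genes and that of the combination for 864. The log2 differences for poly I:C were -2.72 for Csf1r, -3.62 for Htr7, -2.56 for C1qa, -2.54 for Ctss and -1.76 for Atp13a2. For the combination they were 0.87 for Cdkn1b, -2.88 for Htr7, -2.47 for Nfam1, -6.35 for Ngp and -2.87 for Ccr2.

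The first pattern weighed is the response of MT tumours to poly I:C, given that 3 of 4 controls but no poly I:C or combination library had high Sox10. An uneven spread of Sox10-high and Krt5-high cells could be a cause. For poly I:C 1569 genes were called with the Krt5 to Sox10 covariate, and 811 of them were among the 3500. The median of the 3500, each in its own direction, fell from 0.957 to 0.563. The 811 were picked by keeping their call with the covariate, so they do not test the spread by themselves. The kept median shows only that the ratio, as a covariate, did not take up all of the difference. Among controls only replicate 4 was low in Sox10, so the adjusted contrast leans on few libraries. For the combination (0 genes called, median 1.16 to 0.597) an uneven spread cannot be told apart. Fry still called the granule genes higher with the covariate (adjusted p = 0.00111 for poly I:C and 0.000165 for the combination). This does not decide whether the spread caused their rise. Camp and Prtn3 were lower before and turned sign with the covariate. Of 11 single genes 3 and 0 were called, and a first rule on that count left the spread open. Exchanged labels between arms could place such libraries wrongly. A swap of a Sox10-high library into those arms is not seen, as 0 poly I:C or combination libraries had Sox10 above 10 CPM. That value is part of the split itself, so it does not test other exchanges. An effect of poly I:C on which tumour cells are present might also explain the split, and cannot be told apart from an uneven spread, since the arms carry both and the exact permutation p = 0.00295 for Sox10 (8 against 8 libraries) only restates the split that prompted it.

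The next pattern is that strain and cell line tags name the other model than the titles. Exchanged titles could be the reason, but the lowest H2-Ea-ps in a library titled 4T1 was 214 CPM, and BALB/c mice express this locus. Exchanged tags may be the reason instead, since the highest value in a library titled MT was 53 CPM. The lowest value there was 5.24 CPM, so the models differ in level and not in presence. The level that FVB mice would give was not tested.

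The last pattern is the response of 4T1 tumours to poly I:C beside muscle and lymphoid markers. Skeletal muscle in some tumour pieces could be a cause. Without the 5 libraries with Acta1 above 10 CPM the median change of the called genes, each counted in its own direction, was 0.645 against 0.757. Lymphoid tissue might be a cause too, and without the 3 libraries with Igkc above 100 CPM that median was 0.719. The counts of called genes given above fell in both fits. The genes were called in a fit that held the retained libraries too, so a kept median was favoured in advance and excludes neither cause.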

How the results depend on the processing

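A limit of all comparisons is that 4 libraries per group vary widely. Counts of called genes moved with single libraries, while the direction of most named called genes and called gene lists did not. Across alternatives fixed before the data were examined, 0 of the named genes that were called turned direction. These genes were named for a large fold or a small p, and the alternatives used mostly the same libraries. A kept direction was thus favoured in advance, and it says little about the other called genes. For gene lists 4 results did, each with 1 library left out. Only called genes were checked in this way, so the direction of the other named genes was not tested. No camera call held with an estimated correlation (272 of 272 calls weaker), and 82 of 272 held with fry. The cause of each changed count was not tested, and fits with fewer libraries have less power by construction.

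DESeq2 gave 175 for 4T1 phenformin, 1959 for 4T1 poly I:C, 391 for 4T1 combination and 960 for 4T1 combination against poly I:C. It gave 179 for 4T1 combination against phenformin, 36 for 4T1 interaction, 19 for MT phenformin and 2901 for MT combination. It gave 3 for MT combination against poly I:C, 262 for MT combination against phenformin, 33 for MT interaction and 30 for the model difference for phenformin. It gave 2098 for the model difference for combination. DESeq2 size factors gave 101 for 4T1 combination against poly I:C. Without a low-count filter there were 2 for 4T1 phenformin, 364 for MT combination, 6 for MT combination against phenformin and 465 for the model difference for combination. At least 1 CPM in 4 libraries gave 198 for 4T1 combination against poly I:C. With the replicate number as a block, although the numbers do not pair samples, there were 3 for 4T1 combination against poly I:C, 625 for MT combination and 5 for MT combination against phenformin. Fits of only the groups compared gave 3 for 4T1 phenformin, 401 for 4T1 poly I:C, 32 for 4T1 combination and 0 for 4T1 combination against poly I:C. It gave 14 for 4T1 combination against phenformin, 51 for MT combination and 0 for MT combination against phenformin.

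Leaving out each library in turn gave 289 to 1986 for 4T1 poly I:C (1102 with all), 0 to 1 for 4T1 combination (0 with all), 0 to 19 for 4T1 interaction (0 with all) and 1 to 1412 for 4T1 combination against poly I:C (43 with all). It gave 1512 to 6256 for MT poly I:C (3500 with all), 19 to 5375 for MT combination (1096 with all), 1 to 86 for MT combination against phenformin (19 with all) and 230 to 4474 for the model difference for combination (864 with all). It gave 0 to 1 for the model difference for phenformin (0 with all) and 1199 to 4438 for the model difference for poly I:C (2108 with all). Some gene lists turned direction in the test with 1 library left out. The median log2 fold change of T cell markers in MT phenformin ran from -1.0 to 2.56 (-1.0 without MT phenformin replicate 4). The median log2 fold change of epithelial markers in 4T1 phenformin ran from -0.45 to 0.0483 (0.0483 without 4T1 phenformin replicate 2). The median log2 fold change of interferon-stimulated genes in MT combination against poly I:C ran from -0.36 to 0.16 (0.16 without MT combination replicate 1). The median log2 fold change of interferon-stimulated genes in MT interaction ran from -0.38 to 0.0559 (0.0559 without MT combination replicate 1).

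Voom with library quality weights, chosen after seeing the data, called 2863 for 4T1 poly I:C, 226 for 4T1 combination, 1577 for 4T1 combination against poly I:C and 2 for 4T1 interaction. It gave 10642 for MT poly I:C, 9378 for MT combination, 973 for MT combination against poly I:C and 5486 for MT combination against phenformin. It gave 8119 for the model difference for poly I:C and 7366 for the model difference for combination.

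The Krt5 to Sox10 ratio as a covariate, chosen after seeing the data, gave 1569 for MT poly I:C, 0 for MT combination and 1 for MT combination against phenformin. It gave 1100 for the model difference for poly I:C and 111 for the model difference for combination. Some results turned direction in the test, with the median log2 fold changes given here. In MT poly I:C they were T cell markers -0.44. In MT combination they were T cell markers 0.26 and B and plasma cell markers 1.73. In MT combination against phenformin they were dendritic cell markers -0.12, T cell markers -0.00940, B and plasma cell markers 0.32, keratinocyte and skin markers -0.17 and cholesterol synthesis genes 0.0200. In the model difference for poly I:C they were T cell markers 0.97 and keratinocyte and skin markers -0.18. In the model difference for combination they were cholesterol synthesis genes -0.0675.

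Leaving out the MT libraries with Sox10 above 10 CPM, chosen after seeing the data, gave 0 for MT poly I:C, 0 for MT combination and 0 for MT combination against phenformin. It gave 450 for the model difference for poly I:C and 3 for the model difference for combination. Some results turned direction in the test, with the median log2 fold changes given here. In MT phenformin they were mitochondrially encoded genes -0.76 and S phase genes 0.16. In MT poly I:C they were T cell markers -0.34. In MT combination they were T cell markers 0.0953, B and plasma cell markers 0.74 and Pmvk 0.0746. In MT combination against phenformin they were MHC class II antigen presentation -0.0178, neutrophil effector and oxidative burst genes -0.0322, dendritic cell markers -0.91, T cell markers -0.88, B and plasma cell markers -1.08, adipocyte markers -0.48, mitochondrially encoded genes 0.45, glycolysis genes 0.28, hypoxia-responsive genes 0.30 and cholesterol synthesis genes 0.38. In MT interaction they were interferon-stimulated genes 0.37 and mitochondrially encoded genes 0.65. In the model difference for phenformin they were S phase genes -0.17. In the model difference for poly I:C they were T cell markers 0.88 and keratinocyte and skin markers -0.42. In the model difference for combination they were B and plasma cell markers -4.07 and cholesterol synthesis genes -0.15.

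Leaving out the 4T1 libraries with Acta1 above 10 CPM, chosen after seeing the data, gave 1 for 4T1 phenformin, 0 for 4T1 poly I:C and 0 for 4T1 combination against poly I:C. It gave 1 for the model difference for phenformin, 927 for the model difference for poly I:C and 48 for the model difference for combination. Some results turned direction in the test, with the median log2 fold changes given here. In 4T1 combination they were interferon-stimulated genes 0.0438 and MHC class I antigen presentation -0.00277. In 4T1 combination against poly I:C they were MHC class II antigen presentation 0.00704. In 4T1 combination against phenformin they were interferon-stimulated genes 0.0286. In 4T1 interaction they were MHC class I antigen presentation -0.0209 and glycolysis genes -0.0131.

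Leaving out the 4T1 libraries with Igkc above 100 CPM, chosen after seeing the data, gave 259 for 4T1 poly I:C, 1 for 4T1 combination against poly I:C and 447 for the model difference for combination. Some results turned direction in the test, with the median log2 fold changes given here. In 4T1 phenformin they were epithelial markers 0.17. In 4T1 interaction they were B and plasma cell markers 0.46.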

Other observations

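All tests in this part were chosen only after the results were seen.

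Marker genes not in any list separated the models. Trp53 was 35.4 to 51.4 CPM in the libraries titled 4T1 and 91.6 to 132 CPM in those titled MT, and Cdkn2a 0.134 to 0.856 and 13.4 to 111 CPM.

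Libraries of the compared groups were regrouped in every possible way, or in 40 or 100 ways for the larger designs, to ask how often regroupings reach the real count. No other did for poly I:C in 4T1 tumours, with 1 of 35 groupings (the real one) giving 1102 genes and the highest other 1. The same held for poly I:C in MT tumours, with 1 of 35 at 3500 and the highest other 0. It also held for the model difference in the response to poly I:C, with 1 of 40 at 2108 and the highest other 1547. For the controls of both models it was 1 of 35 at 9829, with the highest other 2507. A share of 1 in 35 or 1 in 40 is the smallest that these regroupings allow. For poly I:C in MT tumours the real groups also differ in Sox10, so a chance spread of Sox10-high libraries over the arms is not excluded. The same limit holds for the model difference in the response to poly I:C, which contains that MT contrast.

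Chance also cannot be excluded for 4 other counts, which regroupings reached. For the combination against poly I:C in 4T1 tumours 3 of 35 groupings gave 43 genes or more, and the highest other was 345. In MT tumours 2 of 35 gave 1096 or more for the combination (highest other 2883), and 3 of 35 gave 19 or more for the combination against phenformin (2937). For the model difference in the response to the combination 3 of 40 gave 864 or more (1285).

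Where the real count was 0 every regrouping gives as many, so these decide nothing. That was all 35 for phenformin (highest other 3), the combination (0) and the combination against phenformin (43) in 4T1 tumours, and all 100 for the interaction (1). In MT tumours it was all 35 for phenformin (3616) and the combination against poly I:C (0), and all 100 for the interaction (4557). For the model difference in the response to phenformin it was all 40 (1359). Regroupings that call far more genes than the real groups, as for phenformin, the interaction and the combination against phenformin in MT tumours, point to a structure of the samples other than the arms.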
